A study of Homo sapiens with 6 samples.

How the data were processed

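The data are RNA-seq counts of 6 libraries of MDA-MB-231 cells, 3 treated with DMSO and 3 with 50 nM panobinostat for 24 h. Per the labels' protocols, cells grew in DMEM/F-12 medium with serum, RNA was extracted with a column kit, and libraries were made with a stranded poly(A) mRNA kit and sequenced on an Illumina HiSeq. The labels assign each library to its treatment, and the series' design text says the conditions were repeated independently.

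The authors deposited 1 table of raw counts per gene, not normalised, which its name attributes to featureCounts. Per the submitters' processing notes, the genome build was GRCh38.p14 and FastQC was used. The aligner, the gene annotation, the versions and the strand setting of the counting are not given in the sources used here. The same deposited table holds the authors' own comparison, with a mean normalised signal per gene, log2 fold changes with their SE, a score that equals their quotient, and p-values with their adjusted values. The tool behind that comparison is not given in the sources used here. The counts and the comparison are keyed by separate gene identifier columns. The columns carry the same identifier in the first 61 lines and differ from line 62 on, because 148 of the 30199 lines of the comparison repeat an identifier. Taken line by line, the authors' log2 fold changes had a correlation of 0.017 across genes with those computed from the counts, and 0.967 when matched by identifier, so identifiers were matched throughout. A deposited sum column holds 76184320 counts, 23441472 more than the 52742848 in the 6 libraries. Among 3913 genes with a sum of 1 count, the authors' mean takes 11 values, of which 6 belong to the libraries used here and 5 do not. These further libraries were not analysed here. The table holds 30051 genes, of which 1378 have 0 counts in the 6 libraries.

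Gene symbols came from a reference table matched by Ensembl identifier, which gave 29707 identifiers a symbol, 254 of them shared. Coordinates are those of the RefSeq annotation on GRCh38.p14. Gene type, genomic span, transcript length and GC content came from GENCODE release 29.

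Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM scaling, treatment as the only term). The filterByExpr filter kept 13341 genes and left out 16710. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and a size of at least 2-fold was counted beside that. At an unadjusted p under 0.05 there were 8519 genes. The SE of a log2 fold change was taken from the estimate and its F statistic. The biological coefficient of variation was 0.112, and 0.028 without panobinostat replicate 4. CPM in the report are counts divided by the library total times its TMM factor, scaled to 1000000, and those behind the shares of panobinostat replicate 4 are divided by the plain total. The smallest p that an exact test of 3 against 3 libraries allows is 0.1, so no exact test was used.

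The groups, the design, the 43 gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. The rule names the 8 largest rises and falls among called genes with a symbol, at least 10 CPM and no overlap between groups, up to 4 called members of each list in each direction at 1 CPM or more, a fixed set of genes, and the members of a list where 5 or fewer go against the others or were not called. A further 10 genes, IFT88, IFT20, SRSF4, SRSF7, CCNE1, RRM2, ATP5F1D, NDUFB10, COX6A1 and COX5B, were chosen after their values were seen. Some genes that the rule names are not reported here, and they stay in the counts of their lists. The 38 lists with at least 4 tested members were tested with camera of limma 3.58.1 against all tested genes, with an inter-gene correlation preset at 0.01 and Benjamini-Hochberg adjustment over the lists. The range given beside a list's adjusted p is over its alternatives that keep the preset correlation, and that beside a gene's is over all its alternatives. With the correlation estimated from the data, camera called 0 of the 38 lists, and 1 list had an unadjusted p under 0.05. In that form the test rests on the few residual degrees of freedom of 6 libraries and could call little here. A list not called by it is therefore not shown to be unchanged. fry, which asks whether the members of a list move one way on balance and does not compare them with other genes, called 23 lists higher and 13 lower. Adjusted over the list alone, 25 of the 42 lists with a tested member kept their counts and no count changed by more than 4. The filter keeps a gene near absent in DMSO only where panobinostat raises it. This favours rises in lists of which many members were not tested. Among these are the ERBB ligands (6 tested of 10 with a row), leukocyte markers (6 of 22), checkpoint ligands (11 of 20) and stem cell markers (13 of 18).

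Alternatives were DESeq2 size factors, upper-quartile factors or library size only in the same fit, no filter, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, and leaving out each library in turn. With the replicate number as a block, only replicates 1 and 2 inform the treatment effect, and little is left to estimate the spread. The low ends of gene ranges such as those of HAS2 and RCSD1 come from that fit and are not to be read as strength. The voom fit with library quality weights was added after the data were seen. The median log2 fold change of the tested genes was 0.003, and lay between −0.003 and 0.033 under the other scalings.

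Depth was 5389638 to 15106148 counts per library. In simulated counts for the 13341 tested genes at these depths, with a coefficient of variation of 10%, the test of panobinostat against DMSO recovered 47% of genes changed by 0.5 and 93% of genes changed by 1 on the log2 scale, and called 0.046% of the unchanged genes. Only 200 genes and a list of 40 were changed in the simulation, and every library had the same spread, with none like panobinostat replicate 4. With so few changed genes the adjusted p threshold is stricter than in the data, so these shares do not carry over to it. Ratios of genes with 1 to 3 counts in a group have 95% exact intervals, and the floor is 3 counts over the group. These intervals and floors cover counting error only. Each p-value of a gene measures the spread between these libraries. A camera p-value compares the members of a list with the other tested genes and rests on the correlation set for them. The estimated correlations had a median of 0.085, above the preset 0.01, and that of G2/M and mitosis was 0.713. The preset list p-values are therefore too small where members move together. The estimates also hold the spread that panobinostat replicate 4 adds, so they may overstate the correlation, by how much is not known.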

Results

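RNA was sequenced from MDA-MB-231, a human triple-negative breast cancer line of the claudin-low subtype, which has weak epithelial junctions and mesenchymal features. Cells received the solvent DMSO or 50 nM panobinostat, an inhibitor of most histone deacetylases (HDACs), for 24 h. There were 3 libraries per treatment, DMSO replicates 1, 2 and 3 and panobinostat replicates 1, 2 and 4, and the labels call the conditions independently repeated. Total counts per library were 11996519, 7113569 and 6514568 in DMSO and 15106148, 5389638 and 6622406 in panobinostat, in the order of their numbers. The comparison asks which transcripts changed under the inhibitor, and the series title names HER3, the receptor encoded by ERBB3. Every log2 fold change is panobinostat over DMSO and is given as estimate ± SE. Levels are counts scaled to a TMM-adjusted library total of 1000000 (CPM), as mean ± SD, with n = 3 per group throughout.

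The libraries separated by treatment, with panobinostat replicate 4 in between. On the first principal component, which held 87.5% of the variance of log2 CPM, the DMSO libraries lay at −47.6, −49.1 and −48.4, panobinostat replicates 1 and 2 at 62.9 and 63.9, and panobinostat replicate 4 at 18.3. Across genes, which are not independent replicates, the Pearson correlation of log2 CPM was 0.992 to 0.993 among DMSO libraries and 0.993 between panobinostat replicates 1 and 2. It was 0.974 and 0.972 between panobinostat replicate 4 and replicates 1 and 2, and 0.962 to 0.964 between panobinostat replicate 4 and the DMSO libraries. Chi-square per gene was 1.23 to 1.70 within DMSO and 1.53 between panobinostat replicates 1 and 2, so no pair differed by less than sampling noise. It was 17.6 and 11.9 between panobinostat replicate 4 and replicates 1 and 2. Over the 1698 genes at least 2-fold higher when panobinostat replicate 4 was left out, the median log2 change over the DMSO mean was 1.53, 1.54 and 1.01 in panobinostat replicates 1, 2 and 4. Over the 1193 genes at least 2-fold lower it was −1.28, −1.30 and −0.51.

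**Figure D1:**
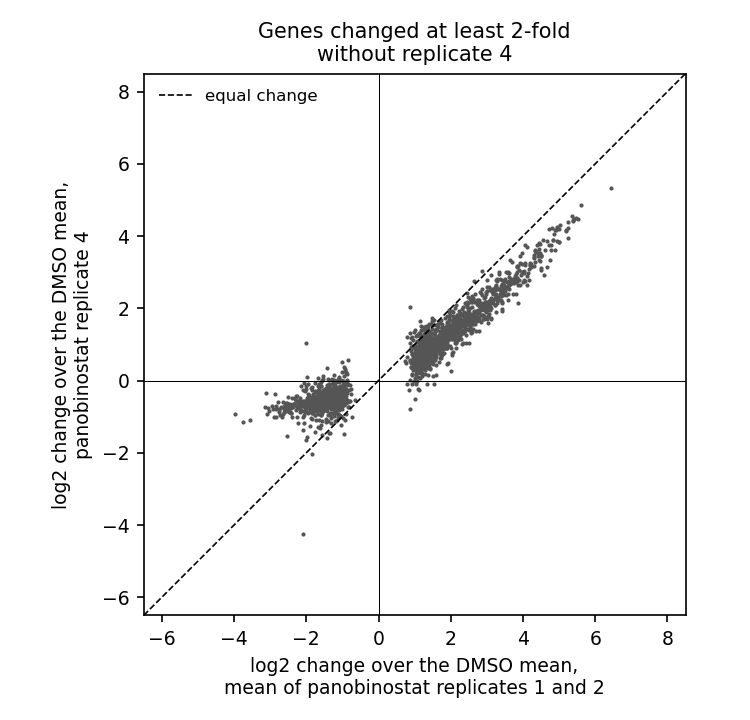
Each point is a gene changed at least 2-fold when panobinostat replicate 4 was left out (1698 higher, 1193 lower), with its log2 change over the DMSO mean in panobinostat replicates 1 and 2 (mean, x axis) and in panobinostat replicate 4 (y axis). The dashed line marks equal change; the median of the higher genes is 1.53, 1.54 and 1.01 in replicates 1, 2 and 4, and that of the lower genes −1.28, −1.30 and −0.51.

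Panobinostat changed the expression of 7853 of 13341 tested genes (58.9%), 4032 higher and 3821 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p under 0.05), and 5488 were not called. At least 2-fold changes were found in 1451 higher and 622 lower genes. The largest rises among genes of at least 10 CPM were in DACT3, an inhibitor of Wnt signalling (6.83 ± 0.49, from 0.378 ± 0.168 to 42.1 ± 16.1 CPM), C7orf57 (6.77 ± 0.54), EFCAB12 (6.35 ± 0.49), EPHB3, an ephrin receptor (6.01 ± 0.52), VWA5B2 (5.98 ± 0.48), TPPP, a tubulin polymerisation protein (5.79 ± 0.33, from 0.575 ± 0.132 to 33.2 ± 9.15 CPM), HES7, a transcriptional repressor of the segmentation clock (5.76 ± 0.56), and TJP3, a tight junction scaffold (5.75 ± 0.44). C7orf57 had 2 counts in DMSO and 277 in panobinostat, a ratio of 128 with a 95% counting interval of 35.2 to 1064. The largest falls were in CLCF1, a cytokine of the interleukin-6 family (−2.56 ± 0.59, from 19.7 ± 0.993 to 3.75 ± 4.32 CPM), HAS2, a hyaluronan synthase (−2.34 ± 0.66), the antisense gene CARD8-AS1 (−2.17 ± 0.52), RCSD1 (−1.97 ± 0.52), INO80D, a subunit of a chromatin remodeller (−1.96 ± 0.38), CBR3, a carbonyl reductase (−1.96 ± 0.47), ZFX, a zinc finger transcription factor (−1.96 ± 0.42), and HMGA2, an architectural chromatin protein (−1.93 ± 0.52, from 154 ± 3.59 to 41.1 ± 38.5 CPM). CARD8-AS1 is uncertain, because the strand setting of the counting is not given in the sources used here. The 3 panobinostat values did not overlap the 3 DMSO values in 9200 of the 13341 tested genes (69.0%), where chance gives 10% for 3 against 3. Of the 228 called genes named in the text, some of them chosen for not overlapping, PSMB10 was the only one with an overlap. Without panobinostat replicate 4, 5024 genes were higher and 4969 lower, 1698 and 1193 of them at least 2-fold, and 7836 of the 7853 calls were kept in the same direction. The count of genes at least 2-fold lower was 328 without panobinostat replicate 1 and 412 without panobinostat replicate 2. Without panobinostat replicate 4 the log2 fold change was −4.06 for CLCF1, −4.04 for HAS2, −3.32 for CARD8-AS1, −3.06 for RCSD1 and −2.98 for HMGA2. With the replicate number as a block it was −4.01 for CLCF1, −4.07 for HAS2, −3.27 for CARD8-AS1, −3.14 for RCSD1, −2.96 for CBR3 and −2.97 for HMGA2. With library quality weights it was −3.90 for CLCF1, −3.94 for HAS2, −3.02 for RCSD1 and −2.94 for HMGA2. HAS2 lost its call without DMSO replicate 1, DMSO replicate 2 or DMSO replicate 3 (edgeR adjusted p = 0.0501 to 0.0608, and 1.29e-169 to 0.173 over all its alternatives). RCSD1 lost its call without DMSO replicate 1 (edgeR adjusted p = 0.0537, and 5.80e-82 to 0.144 over all its alternatives). CLCF1, HAS2, CARD8-AS1, RCSD1, CBR3, ZFX and HMGA2 were not called with no filter (edgeR adjusted p = 0.0522 to 0.173, and up to 0.173 over all their alternatives).

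**Figure D2:**
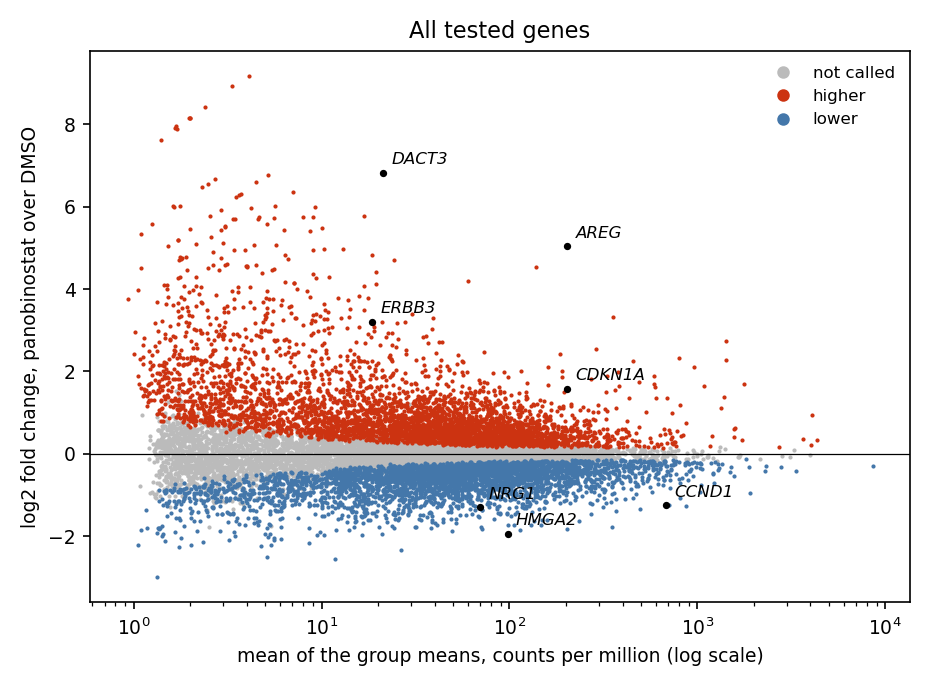
Log2 fold change of panobinostat over DMSO against the mean of the group means in CPM (log scale) for the 13341 tested genes, with 4032 called higher, 3821 called lower and 5488 not called. The rises reach further than the falls, and fold changes of genes with few or no counts in 1 group depend on the prior count of the fit. The intermediate level of panobinostat replicate 4 also limits how far the panobinostat mean can fall. Without that library CLCF1 went from −2.56 to −4.06, while DACT3 went from 6.83 to 7.09.

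ERBB3, the gene of the HER3 receptor, rose 9.23-fold, from 3.68 ± 0.203 CPM in DMSO to 33.6 ± 12.2 CPM in panobinostat (log2 fold change 3.21 ± 0.31, edgeR adjusted p = 0.000631, higher in 3 of 3 libraries). Its panobinostat values were 41.1, 40.3 and 19.6 CPM in replicates 1, 2 and 4, and the log2 fold change without replicate 4 was 3.48. In the same receptor family EGFR fell from 593 ± 17.6 to 344 ± 81.9 CPM (−0.79 ± 0.14, edgeR adjusted p = 0.00348) and ERBB2 from 62.4 ± 1.21 to 43.6 ± 4.36 CPM (−0.52 ± 0.09, edgeR adjusted p = 0.00306). Of the 3 ERBB receptors tested, 1 rose, 2 fell and 0 were not called, the same adjusted over the list alone, and the list was too short for a list test. ERBB4 was too low to be tested, with 3 counts in DMSO and 15 in panobinostat, a ratio of 4.63 with a counting interval of 1.31 to 24.9. Among the ligands, AREG, which encodes the EGFR ligand amphiregulin, rose from 12.1 ± 1.91 to 394 ± 122 CPM (5.05 ± 0.27), and EREG, the epiregulin gene, from 71.6 ± 2.97 to 152 ± 26.6 CPM (1.09 ± 0.13). NRG1, which encodes the HER3 and HER4 ligand neuregulin 1, fell from 98.9 ± 0.752 to 40.9 ± 22.3 CPM (−1.29 ± 0.30), while its relative NRG2 rose (0.89 ± 0.24, edgeR adjusted p = 0.0137). HBEGF (0.10 ± 0.07) and TGFA (−0.16 ± 0.10) were not called. Of the 6 ligands tested, 3 rose, 1 fell and 2 were not called, the same adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.0636), although it was without panobinostat replicate 1 (0.0458) or panobinostat replicate 2 (0.0252), while without panobinostat replicate 4 it was not (0.315), in a range of 0.0252 to 0.371 over its alternatives, and it had an adjusted p = 0.491 with an estimated correlation in all libraries. NRG2 lost its call without DMSO replicate 1, DMSO replicate 3 or panobinostat replicate 1 (edgeR adjusted p = 0.0531 to 0.0795, and 3.45e-05 to 0.0795 over all its alternatives). On GRCh38.p14, the protein-coding gene ERBB3 lies on chromosome 12 from 56080108 to 56103505, EGFR on chromosome 7 from 55019017 to 55211628, ERBB2 on chromosome 17 from 39688094 to 39728658, NRG1 on chromosome 8 from 31639245 to 32774046 and AREG on chromosome 4 from 74445136 to 74455005. NRG1 was not called with no filter (edgeR adjusted p = 0.108, and 5.80e-132 to 0.108 over all its alternatives).

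**Figure D3:**
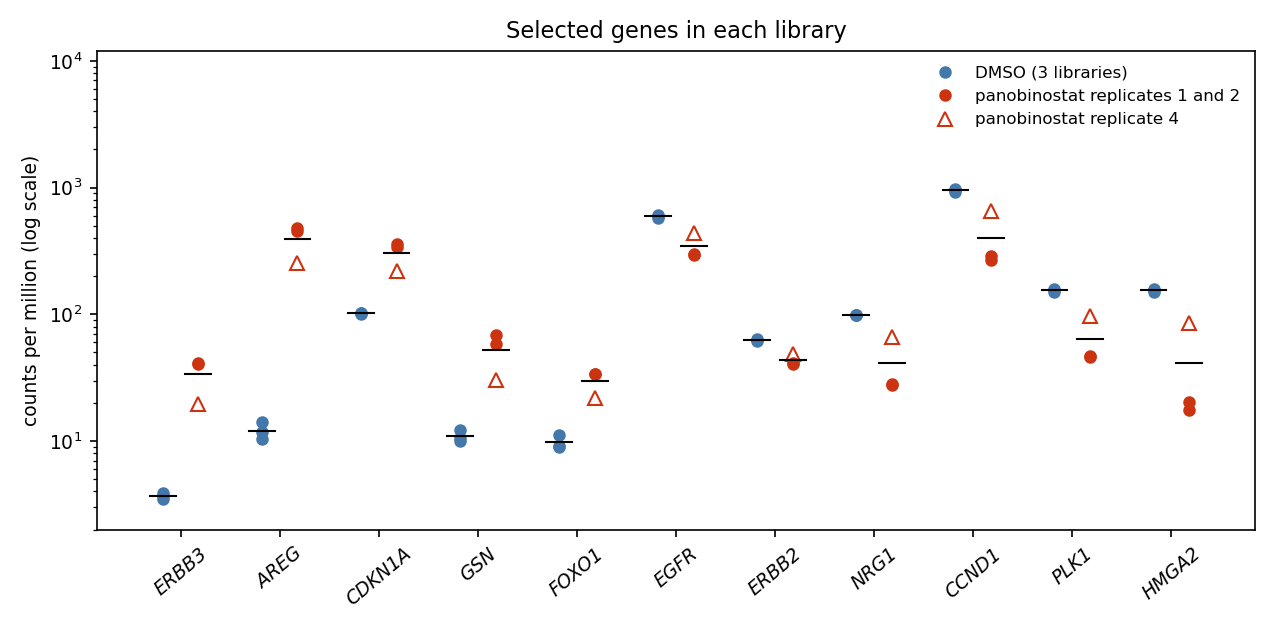
CPM (log scale) of 11 genes in each library, DMSO (3 libraries) at the left and panobinostat (replicates 1 and 2 as points, replicate 4 as a triangle) at the right of each gene, with the group mean as a line. ERBB3 rose from a mean of 3.68 to 33.6 CPM, EGFR fell from 593 to 344 CPM, and the triangle lies between the panobinostat points and the DMSO points in each of these genes.

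Other receptor tyrosine kinases rose more often than they fell. EPHB3 was among the largest rises, and PDGFRB, a platelet-derived growth factor receptor (3.14 ± 0.44), FGFR3 (3.02 ± 0.31) and FGFR4 (2.22 ± 0.25), both fibroblast growth factor receptors, also rose. IGF1R, the insulin-like growth factor receptor gene (−0.36 ± 0.08), AXL (−0.34 ± 0.08), TYRO3 (−0.37 ± 0.13) and EPHA2 (−0.23 ± 0.06) fell. Of the 25 tested among the 42 of the list, 13 rose, 4 fell and 8 were not called, the same adjusted over the list alone. The list had 40 genes with a row of counts. The filter favours rises among its weakly expressed members, such as EPHB3 at 0.198 CPM in DMSO. The list had a median log2 fold change of 0.41 (camera adjusted p = 0.0246, 0.00240 to 0.0766 over its alternatives, and adjusted p = 0.491 with an estimated correlation). This call was lost with limma-voom (adjusted p = 0.0766), with library quality weights (0.0612) and with the replicate number as a block (0.0535). Without panobinostat replicate 4 the median was 0.48, with 16 higher and 6 lower. FOXO targets rose as a group: of 24 tested, 16 rose, 5 fell and 3 were not called, the same adjusted over the list alone. The median log2 fold change was 0.85 (camera adjusted p = 0.000260, 7.69e-08 to 0.0104 over its alternatives, and adjusted p = 0.491 with an estimated correlation). The median was 0.98 without panobinostat replicate 4. SESN3, a sestrin of nutrient sensing (3.79 ± 0.27), ERBB3 itself, FOXO6 (2.88 ± 0.35), CITED2 (1.99 ± 0.19) and FOXO1 (1.61 ± 0.20) rose. PIK3CA, the p110-alpha subunit gene (−0.94 ± 0.20), CDKN1B (−0.78 ± 0.17), CCNG2 (−0.39 ± 0.08), IGF1R and RBL2 (−0.28 ± 0.10) fell, and FOXO3 (0.09 ± 0.10), PINK1 (0.21 ± 0.10) and INSR (−0.19 ± 0.09) were not called. TYRO3 and RBL2 lost their calls without each library in turn except panobinostat replicate 4 (edgeR adjusted p = 0.0643 to 0.143, and 0.000319 to 0.143 over all their alternatives). EPHA2 lost its call without each library in turn except DMSO replicate 1 and panobinostat replicate 4 (edgeR adjusted p = 0.0574 to 0.0646, and 3.80e-17 to 0.0646 over all its alternatives). TYRO3 and RBL2 were not called with the DESeq2 Wald test (DESeq2 adjusted p = 0.0502 to 0.0693). RBL2 was not called with library size only (edgeR adjusted p = 0.0675). RBL2 was not called with upper-quartile factors (edgeR adjusted p = 0.0558).

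Of the 34 PI3K, AKT and mTOR pathway genes tested, 7 rose, 14 fell and 13 were not called, and adjusted over the list alone 7 rose and 15 fell (camera adjusted p = 0.329). Without panobinostat replicate 4, 12 rose and 17 fell. PIK3CD, the p110-delta gene (1.09 ± 0.14), and the insulin receptor substrate gene IRS2 (1.01 ± 0.15) rose, while PIK3CA and TRIB3, an AKT-binding pseudokinase (−1.19 ± 0.21), fell. The MAPK feedback genes, which report ERK output, mostly fell. Of 19 tested, 4 rose, 13 fell and 2 were not called, and adjusted over the list alone 5 rose and 13 fell, but the list was not called (camera adjusted p = 0.0977). It was called without panobinostat replicate 4 (0.0328), with the replicate number as a block (0.0282), with library quality weights (0.0414) and with no filter (0.0130), in a range of 0.0130 to 0.112 over its alternatives. With an estimated correlation it was not called, at adjusted p = 0.510 with all libraries and adjusted p = 0.568 without panobinostat replicate 4. CCND1, the cyclin D1 gene, fell from 955 ± 26.7 to 403 ± 215 CPM (−1.25 ± 0.31), as did FOSL1, an AP-1 subunit gene (−1.21 ± 0.25), and SPRY2, an ERK pathway antagonist (−0.71 ± 0.13). The phosphatases DUSP5 (1.65 ± 0.17) and DUSP6 (1.01 ± 0.12), MYC (0.51 ± 0.08) and EPHA4 (0.49 ± 0.15) rose, and EGR1 (−0.09 ± 0.09) and ETV5 (0.16 ± 0.07) were not called. EPHA4 lost its call without each library in turn except DMSO replicate 2 and panobinostat replicate 4 (edgeR adjusted p = 0.0798 to 0.110, and 0.000884 to 0.110 over all its alternatives). CCND1, FOSL1 and EPHA4 were not called with no filter (edgeR adjusted p = 0.0741 to 0.121, and up to 0.121 over all their alternatives). EPHA4 was not called with the DESeq2 Wald test (DESeq2 adjusted p = 0.0601).

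Among the HDAC genes, whose products the drug inhibits, HDAC11 (1.86 ± 0.25), HDAC5 (1.25 ± 0.16), HDAC3 (0.96 ± 0.14) and HDAC1 (0.21 ± 0.07) rose and HDAC7 (−1.21 ± 0.20), HDAC9 (−0.43 ± 0.11) and HDAC6 (−0.36 ± 0.08) fell. HDAC2 (0.03 ± 0.06), HDAC4 (−0.18 ± 0.11), HDAC8 (−0.18 ± 0.09) and HDAC10 (0.68 ± 0.29) were not called. Of 11 tested, 4 rose, 3 fell and 4 were not called, the same adjusted over the list alone (camera adjusted p = 0.730). Without panobinostat replicate 4, 4 rose and 5 fell. Acetyltransferases and bromodomain readers fell as a group: of 17 tested, 2 rose, 12 fell and 3 were not called, the same adjusted over the list alone. Their median log2 fold change was −0.60 (camera adjusted p = 0.00757, 7.53e-05 to 0.0104 over its alternatives, and adjusted p = 0.491 with an estimated correlation). The median was −0.74 without panobinostat replicate 4. The acetyltransferase genes KAT6B (−1.44 ± 0.36), KAT5 (−1.25 ± 0.19) and CREBBP (−1.09 ± 0.21) fell, the coactivator genes NCOA3 (0.75 ± 0.14) and NCOA1 (0.31 ± 0.11) rose, and KAT6A (0.07 ± 0.07), BRD7 (−0.06 ± 0.06) and BRD2 (−0.44 ± 0.21) were not called. HDAC1 and NCOA1 lost their calls without each library in turn except panobinostat replicate 4 (edgeR adjusted p = 0.0643 to 0.141, and 1.64e-08 to 0.270 over all their alternatives). HDAC9 lost its call without DMSO replicate 3 (edgeR adjusted p = 0.0587, and 2.43e-05 to 0.0587 over all its alternatives). HDAC1, KAT6B and NCOA1 were not called with no filter (edgeR adjusted p = 0.123 to 0.270, and 4.47e-101 to 0.270 over all their alternatives). HDAC1 and NCOA1 were not called with the DESeq2 Wald test (DESeq2 adjusted p = 0.0620 to 0.0656).

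Histone genes moved both ways. Of 16 genes tested in a list of linker histones and of replication-independent or polyadenylated histones, 7 rose, 5 fell and 4 were not called, the same adjusted over the list alone (camera adjusted p = 0.195). The list also holds genes of the replication-dependent clusters that are known to give polyadenylated transcripts, among them H1-2, H2BC4, H2BC5 and H2BC12. H1-10 (1.81 ± 0.17) and H2BC5 (1.09 ± 0.21) rose. The centromeric histone gene CENPA (−1.06 ± 0.21), H2AZ1 (−0.51 ± 0.11), MACROH2A1 (−0.24 ± 0.06), H2AX (−0.17 ± 0.07) and H2AZ2 (−0.15 ± 0.05) fell. H3-3A (0.03 ± 0.07), H2BC4 (−0.33 ± 0.28), H1-2 (0.11 ± 0.08) and H2BC12 (0.17 ± 0.10) were not called. Of the 7 other replication-dependent histones tested, whose transcripts mostly lack poly(A) tails, 3 rose, 0 fell and 4 were not called, and adjusted over the list alone 2 rose and 0 fell (camera adjusted p = 0.308). H2BC18 (1.42 ± 0.36), H3C10 (1.18 ± 0.34) and H2AC11 (0.78 ± 0.28) rose, and H2BC11 (0.10 ± 0.19), H4C8 (0.46 ± 0.21), H1-4 (0.76 ± 0.42) and H4C9 (0.11 ± 0.10) were not called. Histone genes have near-identical copies, so their values are uncertain. MACROH2A1 lost its call without DMSO replicate 2 (edgeR adjusted p = 0.0544, and 6.41e-14 to 0.0544 over all its alternatives). H2AX and H2AZ2 lost their calls without each library in turn except panobinostat replicate 4 (edgeR adjusted p = 0.0590 to 0.175, and 1.04e-06 to 0.175 over all their alternatives). H2BC18 lost its call without DMSO replicate 1 (edgeR adjusted p = 0.0550, and 3.20e-05 to 0.0550 over all its alternatives). H3C10 lost its call without DMSO replicate 1, DMSO replicate 2 or panobinostat replicate 1 (edgeR adjusted p = 0.0611 to 0.0992, and 4.27e-07 to 0.0992 over all its alternatives). H2AC11 lost its call without each library in turn except DMSO replicate 3 and panobinostat replicate 4 (edgeR adjusted p = 0.0917 to 0.159, and 0.00103 to 0.159 over all its alternatives). H2AX, H2AZ2 and H2AC11 were not called with no filter (edgeR adjusted p = 0.0547 to 0.103). H2AX, H2AZ2 and H2AC11 were not called with the DESeq2 Wald test (DESeq2 adjusted p = 0.0734 to 0.130). H2AX and H2AZ2 were not called with library size only (edgeR adjusted p = 0.0901 to 0.0935). H2AX and H2AZ2 were not called with upper-quartile factors (edgeR adjusted p = 0.0616 to 0.0634).

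Cell cycle genes fell broadly. Of the 43 G2/M and mitosis genes tested, 0 rose, 38 fell and 5 were not called, the same adjusted over the list alone. The list had a median log2 fold change of −0.78 (camera adjusted p = 7.59e-11, 8.42e-23 to 3.26e-10 over its alternatives, and adjusted p = 0.491 with an estimated correlation). Of the 47 DNA replication and S phase genes tested, 0 rose, 39 fell and 8 were not called, and adjusted over the list alone 2 rose and 40 fell. The median log2 fold change was −0.63 (camera adjusted p = 2.43e-08, 4.10e-16 to 3.94e-08 over its alternatives, and adjusted p = 0.491 with an estimated correlation). Without panobinostat replicate 4 the medians were −0.94 and −0.84. In that fit 0 G2/M and mitosis genes rose and 40 fell, and 4 DNA replication and S phase genes rose and 40 fell. PLK1 (−1.29 ± 0.26) and AURKA (−1.20 ± 0.25), mitotic kinases, and PRC1, a spindle midzone protein (−1.20 ± 0.23), fell, while CDC20 (−0.01 ± 0.05), NEK2 (0.05 ± 0.07), KIF18A (−0.11 ± 0.08), CDC25C (−0.14 ± 0.11) and PTTG1 (0.05 ± 0.06) were not called. GINS3, of the replicative helicase (−1.65 ± 0.33), the repressor E2F8 (−1.61 ± 0.37), UHRF1, which maintains DNA methylation (−1.32 ± 0.35), and CCNE2, a cyclin E gene (−1.13 ± 0.18), fell. The genes that rose when adjusted over the list alone, CCNE1 (0.27 ± 0.10) and RRM2 (0.13 ± 0.05), were named after their values were seen. CDKN1A, the p21 gene, rose from 102 ± 1.01 to 305 ± 76.2 CPM (1.58 ± 0.17, edgeR adjusted p = 0.000701). It lies on chromosome 6 from 36676463 to 36687332. Of the 5 CDK inhibitors tested, 2 rose, 2 fell and 1 was not called, the same adjusted over the list alone (camera adjusted p = 0.852). CDKN2D rose (0.40 ± 0.10), CDKN2C (−0.87 ± 0.15) and CDKN1B fell, CDKN3 (0.12 ± 0.07) was not called, and CDKN2A was not analysed here. PLK1, AURKA, PRC1, E2F8 and UHRF1 were not called with no filter (edgeR adjusted p = 0.0623 to 0.148, and up to 0.148 over all their alternatives).

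Homologous recombination and Fanconi anaemia genes fell as a group: of 37 tested, 4 rose, 24 fell and 9 were not called, and adjusted over the list alone 4 rose and 25 fell. Their median log2 fold change was −0.49 (camera adjusted p = 0.000386, 8.43e-08 to 0.000904 over its alternatives, and adjusted p = 0.491 with an estimated correlation). The median was −0.63 without panobinostat replicate 4. DNA2, a nuclease and helicase of end resection (−1.28 ± 0.23), BRCA2 (−1.15 ± 0.20) and BRCA1 (−0.56 ± 0.13) fell. RAD50 (0.83 ± 0.26), FANCM (0.47 ± 0.11), RAD51C (0.32 ± 0.10) and FANCE (0.30 ± 0.09) rose. RAD50 lost its call without each library in turn except DMSO replicate 3 and panobinostat replicate 4 (edgeR adjusted p = 0.0559 to 0.0750, and 0.00759 to 0.0933 over all its alternatives). RAD51C lost its call without each library in turn except panobinostat replicate 4 (edgeR adjusted p = 0.0563 to 0.0982, and 0.000232 to 0.160 over all its alternatives). FANCE lost its call without DMSO replicate 1, DMSO replicate 3 or panobinostat replicate 1 (edgeR adjusted p = 0.0957 to 0.113, and 6.59e-07 to 0.113 over all its alternatives). RAD50, RAD51C and FANCE were not called with no filter (edgeR adjusted p = 0.0810 to 0.160). RAD50 and RAD51C were not called with the DESeq2 Wald test (DESeq2 adjusted p = 0.0543 to 0.0933).

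Apoptosis genes moved both ways. Of the 23 pro-apoptotic genes tested, 10 rose, 5 fell and 8 were not called, and adjusted over the list alone 10 rose and 8 fell (camera adjusted p = 0.302). The BH3-only gene BMF (2.67 ± 0.27), TP53INP1, a p53 target (1.72 ± 0.20), TNFRSF10B, a TRAIL receptor gene (1.12 ± 0.12), and BCL2L11, the BIM gene (0.87 ± 0.19), rose. The death receptor gene FAS (−1.13 ± 0.29), BID (−0.87 ± 0.19), FADD (−0.66 ± 0.14) and CASP8 (−0.37 ± 0.12) fell. Of the 12 anti-apoptotic genes tested, 2 rose, 7 fell and 3 were not called, the same adjusted over the list alone (camera adjusted p = 0.170, and 0.0371 with no filter, in a range of 0.0371 to 0.180 over its alternatives, and adjusted p = 0.491 with an estimated correlation). CFLAR, a caspase-8 inhibitor (−1.33 ± 0.27), XIAP (−0.85 ± 0.16), the survivin gene BIRC5 (−0.81 ± 0.14), BCL2L1, the BCL-XL gene (−0.78 ± 0.15), and BCL2 (−0.66 ± 0.19) fell. BIRC3 (1.89 ± 0.17) and BCL2A1 (0.73 ± 0.26) rose, and MCL1 (0.07 ± 0.05), BAG1 (0.08 ± 0.08) and BAG3 (−0.13 ± 0.07) were not called. CASP8 lost its call without each library in turn except DMSO replicate 1 and panobinostat replicate 4 (edgeR adjusted p = 0.0905 to 0.1002, and 7.79e-06 to 0.1002 over all its alternatives). BCL2A1 and BCL2 lost their calls without each library in turn except panobinostat replicate 4 (edgeR adjusted p = 0.0537 to 0.164, and 3.42e-19 to 0.164 over all their alternatives). BCL2A1 was not called with the DESeq2 Wald test (DESeq2 adjusted p = 0.0585).

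Epithelial junction genes rose as a group: of 21 tested, 14 rose, 5 fell and 2 were not called, the same adjusted over the list alone. It holds 41 genes, 39 of them with a row of counts. The filter keeps a gene near absent in DMSO only where panobinostat raises it, which favours rises among such genes. The list had a median log2 fold change of 1.49 (camera adjusted p = 0.000260, 5.06e-05 to 0.0340 over its alternatives, and adjusted p = 0.491 with an estimated correlation). The median was 1.54 without panobinostat replicate 4. TJP3, CD24, a surface glycoprotein (4.16 ± 0.25), SPINT1, a protease inhibitor (4.04 ± 0.46), CLDN4, a tight junction claudin (1.64 ± 0.29, from 1.24 ± 0.378 to 4.05 ± 0.821 CPM), and MAL2, of apical transport (5.19 ± 0.63), rose. MAL2 had 2 counts in DMSO and 95 in panobinostat, a ratio of 44.0 with a counting interval of 11.8 to 368, and its log2 fold change was 7.96 without DMSO replicate 2. The desmosomal genes PKP3 (−1.22 ± 0.23) and DSC2 (−1.12 ± 0.19), EPCAM (−0.77 ± 0.17) and SPINT2 (−0.41 ± 0.07) fell, and DSP (0.08 ± 0.07) and CLDN7 (0.01 ± 0.12) were not called. CDH1, the E-cadherin gene, had 1 count in DMSO and 0 in panobinostat, below the floor of 3 counts per group (0.119 and 0.110 CPM), so no change was detectable at this depth. CLDN3 had 1 count in DMSO and 7 in panobinostat, a ratio of 6.48 with a counting interval of 0.833 to 292.

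Mesenchymal genes moved both ways: of 33 tested, 13 rose, 9 fell and 11 were not called, and adjusted over the list alone 14 rose and 9 fell (camera adjusted p = 0.195). SNAI1, the Snail repressor gene (3.58 ± 0.31), the matricellular genes CCN2 (2.27 ± 0.20) and THBS1 (2.10 ± 0.18), and VIM, the vimentin gene (0.16 ± 0.05), rose. PLAU, the urokinase gene (−1.78 ± 0.49, −2.75 without panobinostat replicate 4, −2.74 with the block and −2.69 with quality weights), MMP14 (−1.26 ± 0.27), and the repressor genes ZEB2 (−1.25 ± 0.21) and ZEB1 (−0.91 ± 0.15) fell. Of the 12 luminal markers tested, 4 rose, 7 fell and 1 was not called, the same adjusted over the list alone (camera adjusted p = 0.435). KRT19 (2.42 ± 0.22), GREB1 (1.43 ± 0.34), CA12 (1.26 ± 0.17) and PRLR (1.23 ± 0.27) rose, the transcription factors SPDEF (−1.47 ± 0.24), XBP1 (−1.29 ± 0.26) and GATA3 (−1.19 ± 0.39) fell, and KRT8 (0.06 ± 0.06) was not called. GATA3 was −1.82 without panobinostat replicate 4 and −1.80 with quality weights, and VIM was 0.11 with no filter. ESR1, the oestrogen receptor gene, was too low to be tested, with 5 counts in DMSO and 13 in panobinostat. Of the 12 basal markers tested, 1 rose, 5 fell and 6 were not called, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.302, direction down, mean 0.03 against a median of −0.20). NGFR rose (3.01 ± 0.34), and FOXC1 (−1.03 ± 0.18), EGFR, the laminin gene LAMA3 (−0.31 ± 0.08) and DST (−0.17 ± 0.06) fell. Of the 13 stem cell markers tested, 6 rose, 2 fell and 5 were not called, and adjusted over the list alone 6 rose and 3 fell (camera adjusted p = 0.183). NOTCH3 (3.49 ± 0.28) and SOX2 (2.27 ± 0.30) rose, JAG1 (−0.52 ± 0.08) and BMI1 (−0.47 ± 0.11) fell, and CD44 (0.09 ± 0.05), ITGA6 (−0.05 ± 0.05), HES1 (−0.35 ± 0.14), LGR5 (0.26 ± 0.19) and ALDH1A3 (−0.31 ± 0.33) were not called. VIM and GATA3 lost their calls without each library in turn except panobinostat replicate 4 (edgeR adjusted p = 0.0681 to 0.113, and 8.18e-22 to 0.297 over all their alternatives). LAMA3 lost its call without DMSO replicate 2, DMSO replicate 3 or panobinostat replicate 2 (edgeR adjusted p = 0.0542 to 0.0556, and 2.99e-05 to 0.0556 over all its alternatives). DST lost its call without each library in turn except DMSO replicate 3 and panobinostat replicate 4 (edgeR adjusted p = 0.0820 to 0.137, and 4.38e-14 to 0.137 over all its alternatives). VIM, PLAU and MMP14 were not called with no filter (edgeR adjusted p = 0.0845 to 0.297, and up to 0.297 over all their alternatives). VIM was not called with the DESeq2 Wald test (DESeq2 adjusted p = 0.0689). DST was not called with library size only (edgeR adjusted p = 0.0611).

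Neuronal genes and targets of the repressor REST rose as a group: of 17 tested, 12 rose, 1 fell and 4 were not called, the same adjusted over the list alone. The list holds 57 genes, 46 of them with a row of counts, and the filter favours rises here as in the epithelial list. The median log2 fold change was 2.23 (camera adjusted p = 0.000221, 7.99e-06 to 0.0151 over its alternatives, and adjusted p = 0.491 with an estimated correlation). It was 2.46 without panobinostat replicate 4, where 12 rose and 4 fell. SYT11, a synaptotagmin (4.82 ± 0.32), the vesicle GTPase gene RAB3A (3.27 ± 0.29), L1CAM, an adhesion molecule (3.01 ± 0.38), and CDK5R2 (2.86 ± 0.62) rose. STX1A fell (−0.53 ± 0.12), and SYT1 (0.14 ± 0.21), CRMP1 (−0.25 ± 0.17), VGF (−0.34 ± 0.26) and STMN3 (−0.27 ± 0.26) were not called. Of the 16 cytoskeletal genes tested, 8 rose, 4 fell and 4 were not called, the same adjusted over the list alone (camera adjusted p = 0.0581). The list was called without DMSO replicate 3 (0.0428), panobinostat replicate 1 (0.0297) or panobinostat replicate 2 (0.0323), and with no filter (0.0110), but not without panobinostat replicate 4 (0.352), in a range of 0.0110 to 0.377 over its alternatives, and it had an adjusted p = 0.491 with an estimated correlation in all libraries. GSN, which encodes the actin-severing gelsolin, rose from 10.9 ± 1.20 to 52.4 ± 19.9 CPM (2.28 ± 0.29), as did the microtubule-associated genes MAP1A (4.41 ± 0.35) and MAP2 (3.33 ± 0.21). TUBB6 (−0.78 ± 0.16), DPYSL2 (−0.41 ± 0.09), STMN1 (−0.36 ± 0.07) and MAP1B (−0.35 ± 0.08) fell, and TUBA4A (0.02 ± 0.07) and TMSB15B (−0.20 ± 0.32) were not called.

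Cholesterol synthesis genes rose as a group: of 24 tested, 16 rose, 2 fell and 6 were not called, and adjusted over the list alone 18 rose and 2 fell. Their median log2 fold change was 0.51 (camera adjusted p = 0.00250, 5.62e-05 to 0.00393 over its alternatives, and adjusted p = 0.491 with an estimated correlation). INSIG1, a regulator of sterol sensing (1.54 ± 0.16), IDI1 (1.17 ± 0.13) and HMGCS1 (1.06 ± 0.14), pathway enzymes, rose, and SREBF2, the sterol-responsive transcription factor gene (−0.33 ± 0.08), and FDPS (−0.30 ± 0.07) fell. Lysosome and autophagy genes also rose: of 36 tested, 21 rose, 3 fell and 12 were not called, the same adjusted over the list alone. The list had a median log2 fold change of 0.33 (camera adjusted p = 0.00757, 0.000879 to 0.0143 over its alternatives, and adjusted p = 0.491 with an estimated correlation). TFEB, a master regulator of lysosomal genes (2.94 ± 0.26), ATP6V0A1, a proton pump subunit (1.21 ± 0.14), and MAP1LC3B, an autophagosome marker (1.13 ± 0.12), rose, while TFE3 (−0.50 ± 0.10), ATG7 (−0.30 ± 0.10) and CTSD (−0.30 ± 0.07) fell. Without panobinostat replicate 4 the medians were 0.59 and 0.39. In that fit 19 cholesterol synthesis genes rose and 2 fell, and 23 lysosome and autophagy genes rose and 6 fell. ATG7 lost its call without each library in turn except panobinostat replicate 4 (edgeR adjusted p = 0.0522 to 0.121, and 4.79e-05 to 0.121 over all its alternatives).

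Cytosolic ribosomal protein genes fell slightly: of 57 tested, 0 rose, 41 fell and 16 were not called, and adjusted over the list alone 0 rose and 45 fell. The median log2 fold change was −0.21 (camera adjusted p = 0.000260, 9.37e-09 to 0.000777 over its alternatives, and adjusted p = 0.510 with an estimated correlation). RPL6 (−0.48 ± 0.10) and RPL13A (−0.37 ± 0.07) are examples, and processed copies of these genes can share their reads. Of the 30 proteasome genes tested, 1 rose, 13 fell and 16 were not called, the same adjusted over the list alone, and the list was called lower. Their median log2 fold change was −0.19 (camera adjusted p = 0.0374, 0.00114 to 0.0676 over its alternatives, and adjusted p = 0.504 with an estimated correlation). That call was lost when libraries were scaled by total count only (0.0525) and without DMSO replicate 1 (0.0676). PSMD7 (−0.75 ± 0.17) and PSMD11 (−0.51 ± 0.13) fell and PSMD3 rose (0.23 ± 0.07). Without panobinostat replicate 4 the medians were −0.25 for ribosomal proteins and −0.18 for the proteasome. In that fit 1 ribosomal protein gene rose and 50 fell, and 4 proteasome genes rose and 20 fell. Of the 36 MYC and ribosome biogenesis genes tested, 8 rose, 19 fell and 9 were not called, and adjusted over the list alone 8 rose and 20 fell, and the list was not called (camera adjusted p = 0.0739). It was called without panobinostat replicate 4 (0.0273), with the replicate number as a block (0.0143), with library quality weights (0.0337) and with no filter (0.00431), in a range of 0.00431 to 0.0975 over its alternatives. With an estimated correlation it was not called, at adjusted p = 0.491 with all libraries and adjusted p = 0.568 without panobinostat replicate 4. MYCL (4.39 ± 0.47), ODC1, of polyamine synthesis (1.36 ± 0.15), and MYC rose, and UBTF, a ribosomal RNA transcription factor (−1.41 ± 0.33), and NCL, the nucleolin gene (−0.71 ± 0.14), fell. PSMD3 lost its call without each library in turn except panobinostat replicate 4 (edgeR adjusted p = 0.0528 to 0.0771, and 8.80e-14 to 0.138 over all its alternatives). PSMD3 and UBTF were not called with no filter (edgeR adjusted p = 0.107 to 0.138, and 1.42e-277 to 0.138 over all their alternatives).

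With all libraries, energy metabolism genes were mostly not called or moved both ways. Of the 45 oxidative phosphorylation genes tested, 6 rose, 7 fell and 32 were not called, and adjusted over the list alone 5 rose and 6 fell (camera adjusted p = 0.435, direction down, mean −0.02 against a median of 0.003), among them NDUFA8 (0.44 ± 0.11), a subunit of complex I. With NDUFA8, the genes that rose under both adjustments were ATP5F1D (0.34 ± 0.07), NDUFB10 (0.40 ± 0.09), COX6A1 (0.30 ± 0.09) and COX5B (0.27 ± 0.08), named after their values were seen. Without panobinostat replicate 4, 14 of the oxidative phosphorylation genes rose and 15 fell. Of the 24 glycolysis genes tested, 8 rose, 4 fell and 12 were not called, and adjusted over the list alone 8 rose and 3 fell (camera adjusted p = 0.411). The glucose transporter gene SLC2A3 (1.74 ± 0.17) and ENO2 (1.14 ± 0.15) rose, and PFKL (−0.39 ± 0.08), ENO1 (−0.32 ± 0.06), PFKP (−0.20 ± 0.05) and LDHB (−0.15 ± 0.06) fell. Of the 27 unfolded protein and integrated stress response genes tested, 11 rose, 6 fell and 10 were not called, and adjusted over the list alone 13 rose and 6 fell (camera adjusted p = 0.415). HSPA5, the BiP chaperone gene (1.11 ± 0.13), and ATF3 (0.78 ± 0.22) rose, while XBP1, TRIB3 and ATF4 (−0.60 ± 0.10) fell. Of the 16 heat shock genes tested, 5 rose, 3 fell and 8 were not called, the same adjusted over the list alone (camera adjusted p = 0.443, direction up, mean 0.52 against a median of −0.05). More fell than rose without panobinostat replicate 4, 8 against 6. HSPA12A rose from 3 to 172 counts, a ratio of 53.1 with a counting interval of 17.9 to 260 (5.53 ± 0.48). DNAJB1 (1.89 ± 0.18), the clusterin gene CLU (1.52 ± 0.16), HSPA2 (0.59 ± 0.20) and HSP90AA1 (0.33 ± 0.06) also rose, and HSPA8 (−0.42 ± 0.08), HSF1 (−0.33 ± 0.08) and DNAJA1 (−0.31 ± 0.07) fell. The 3 metallothioneins tested, MT1X (2.24 ± 0.24), MT1E (0.87 ± 0.10) and MT2A (0.38 ± 0.07), rose, also when adjusted over the list alone, and are uncertain because their copies are near-identical. PFKP and COX5B lost their calls without DMSO replicate 2, DMSO replicate 3 or panobinostat replicate 2 (edgeR adjusted p = 0.0546 to 0.0904, and 3.53e-08 to 0.110 over all their alternatives). LDHB lost its call without each library in turn except panobinostat replicate 4 (edgeR adjusted p = 0.0764 to 0.178, and 2.42e-14 to 0.178 over all its alternatives). ATF3 lost its call without DMSO replicate 1, DMSO replicate 2 or panobinostat replicate 1 (edgeR adjusted p = 0.0503 to 0.0751, and 3.72e-10 to 0.0751 over all its alternatives). HSPA2 lost its call without each library in turn except DMSO replicate 2 and panobinostat replicate 4 (edgeR adjusted p = 0.0770 to 0.116, and 0.000825 to 0.116 over all its alternatives). COX6A1 lost its call without DMSO replicate 1, DMSO replicate 3 or panobinostat replicate 2 (edgeR adjusted p = 0.0734 to 0.0914, and 4.99e-06 to 0.0920 over all its alternatives). COX6A1, COX5B and HSPA2 were not called with no filter (edgeR adjusted p = 0.0637 to 0.110). LDHB and HSPA2 were not called with the DESeq2 Wald test (DESeq2 adjusted p = 0.0653 to 0.0722). LDHB was not called with library size only (edgeR adjusted p = 0.0848). LDHB was not called with upper-quartile factors (edgeR adjusted p = 0.0585).

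Interferon and inflammatory genes moved both ways. Of the 29 type I interferon response genes tested, 10 rose, 8 fell and 11 were not called, the same adjusted over the list alone (camera adjusted p = 0.490, direction up, mean 0.12 against a median of −0.08). Without panobinostat replicate 4, 11 rose and 12 fell. OASL (2.25 ± 0.19), ISG15 (1.75 ± 0.18) and IFIT1 (1.51 ± 0.22) rose, and IFIT2 (−1.59 ± 0.38) and IFIT3 (−1.48 ± 0.33) fell. Of the 26 NF-kB and inflammatory genes tested, 14 rose, 7 fell and 5 were not called, and adjusted over the list alone 14 rose and 10 fell (camera adjusted p = 0.0544). The list was called without panobinostat replicate 1 (0.0349) or panobinostat replicate 2 (0.0350), and with a filter of 1 CPM in 3 libraries (0.0495) or with none (0.00166), but not without panobinostat replicate 4 (0.280), in a range of 0.00166 to 0.311 over its alternatives, and it had an adjusted p = 0.491 with an estimated correlation in all libraries. The chemokine gene CCL20 (4.97 ± 0.34), IL1A (2.61 ± 0.21), BIRC3 and PTX3 (1.39 ± 0.14) rose, LIF (−1.50 ± 0.32), CSF3 (−1.45 ± 0.37) and NFKB1 (−1.35 ± 0.30) fell, and IL32 (0.26 ± 0.23), PTGS2 (−0.20 ± 0.12), NFKBIA (−0.19 ± 0.07), IRAK2 (−0.30 ± 0.12) and TNFAIP2 (−0.17 ± 0.07) were not called. Of the 9 antigen presentation genes tested, 0 rose, 3 fell and 6 were not called, and adjusted over the list alone 0 rose and 2 fell (camera adjusted p = 0.183), and the falls were in ERAP2 (−1.28 ± 0.21), PSMB10 (−0.73 ± 0.26) and ERAP1 (−0.45 ± 0.09). Of the 11 checkpoint ligands tested, 7 rose, 1 fell and 3 were not called, the same adjusted over the list alone (camera adjusted p = 0.103, and 0.0456 with no filter, in a range of 0.0456 to 0.150 over its alternatives, and adjusted p = 0.491 with an estimated correlation). TNFSF9 (2.85 ± 0.30), ULBP2 (1.30 ± 0.17) and CD274, the PD-L1 gene (0.73 ± 0.16, from 18.8 ± 1.73 to 31.1 ± 6.45 CPM), rose, PVR fell (−0.30 ± 0.08), and TNFSF4 (−0.03 ± 0.23), PDCD1LG2 (−1.07 ± 0.48) and MICA (0.71 ± 0.68) were not called. PSMB10 lost its call without each library in turn except panobinostat replicate 4 (edgeR adjusted p = 0.0654 to 0.142, and 2.52e-06 to 0.142 over all its alternatives). IFIT2, IFIT3, LIF, CSF3 and NFKB1 were not called with no filter (edgeR adjusted p = 0.0796 to 0.136, and up to 0.136 over all their alternatives).

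Markers of other cell types were mostly too low to be tested. Of the 6 leukocyte markers tested, 3 rose, 1 fell and 2 were not called, the same adjusted over the list alone (camera adjusted p = 0.183), with rises in CORO1A (4.30 ± 0.38), CD14 (2.21 ± 0.36) and LCP1 (1.05 ± 0.15), a fall in LAPTM5 (−0.32 ± 0.09), and no call for CD8A (0.02 ± 0.32) and CSF1R (−0.61 ± 0.38). Of the 12 fibroblast and endothelial markers tested, 5 rose, 3 fell and 4 were not called, and adjusted over the list alone 5 rose and 4 fell (camera adjusted p = 0.191). PDGFRB, COL1A1 (2.13 ± 0.19), KDR (1.96 ± 0.24), COL5A1 (1.30 ± 0.14) and EGFL7 (1.28 ± 0.15) rose, ROBO4 (−1.57 ± 0.35), ENG (−0.49 ± 0.09) and ESAM (−0.29 ± 0.09) fell, and TIE1 (0.10 ± 0.07), RGS5 (−0.02 ± 0.23), COL6A3 (−0.19 ± 0.09) and PECAM1 (−0.58 ± 0.23) were not called. Of the 2 cancer-testis antigens tested, TEX14 rose (2.18 ± 0.25) and MAGEC2 was not called (−0.49 ± 0.29). Of the 2 erythroid, muscle and liver genes tested, CYP1A1 rose (1.64 ± 0.21) and TNNT1 was not called (0.04 ± 0.09). Adjusted over the list alone, these last 2 lists kept those counts. Of the 28 ubiquitous reference genes tested, 3 rose, 10 fell and 15 were not called, the same adjusted over the list alone (camera adjusted p = 0.139, and 0.0110 with no filter, in a range of 0.0110 to 0.197 over its alternatives, and adjusted p = 0.510 with an estimated correlation), with rises in ACTB (0.36 ± 0.06) and SDHA (0.24 ± 0.08) and a fall in POLR2A (−0.68 ± 0.12) among them. Mitochondrial-encoded transcripts were not analysed here. LAPTM5 and ESAM lost their calls without each library in turn except DMSO replicate 2 and panobinostat replicate 4 (edgeR adjusted p = 0.0576 to 0.0816, and 2.81e-15 to 0.0816 over all their alternatives). SDHA lost its call without each library in turn except panobinostat replicate 4 (edgeR adjusted p = 0.0789 to 0.116, and 1.09e-18 to 0.123 over all its alternatives). ROBO4 and SDHA were not called with no filter (edgeR adjusted p = 0.0942 to 0.123, and 1.63e-137 to 0.123 over all their alternatives).

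**Figure D4:**
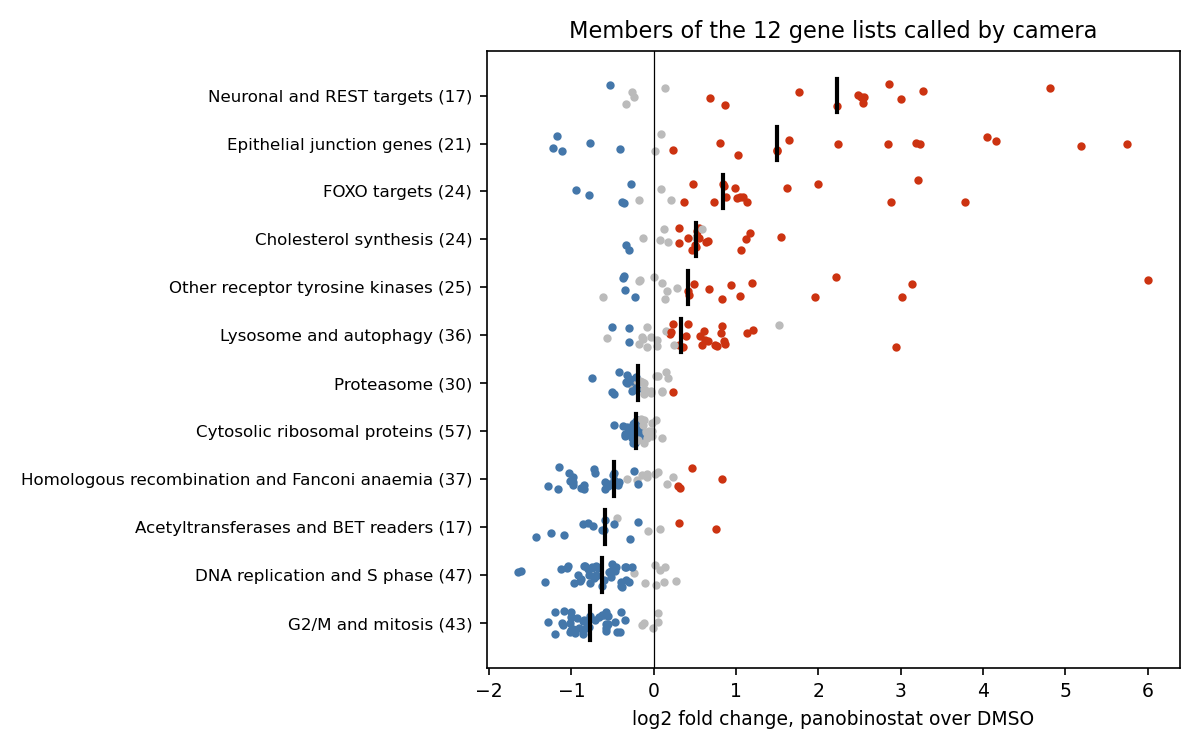
Log2 fold change of panobinostat over DMSO for each tested member of the 12 gene lists called by camera, with called members in red (higher) or blue (lower), members not called in grey and the list median as a bar. The medians run from −0.78 for G2/M and mitosis to 2.23 for neuronal and REST targets, and the number of tested members stands beside each list.

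The authors' deposited table of their own comparison gave ERBB3 a log2 fold change of 2.18 (SE 0.53, adjusted p 0.000339). In the authors' deposited table CDKN1A was at 1.21, MYC at 0.41, IGF1R at −0.33 and HDAC9 at −0.40. Of the 7853 genes called here, 6858 (87.3%) had an adjusted p under 0.05 and the same sign in the authors' deposited table. That table held 7258 genes with an adjusted p under 0.05, 3677 higher and 3581 lower. Over the 2073 genes changed at least 2-fold here, the slope of the log2 fold changes of the authors' deposited table on those from the 6 libraries was 0.690. The authors' deposited table rests on counts of more libraries than these 6, and the others were not analysed here. Its means include these same 6 libraries, so the shared calls are not independent evidence. Which libraries its fold changes compare is not known, so the smaller values and the slope cannot be interpreted further.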

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

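The fit with library quality weights was chosen after the data were seen, and the other alternatives were chosen before. Whether the numbers of the libraries pair them is not known. Same-numbered libraries exist only for replicates 1 and 2, and their deviations from the group means correlated at 0.051 and 0.008. Those of libraries of unlike number correlated at −0.063 to 0.033. The panobinostat mean includes replicate 4, which shifts the deviations of replicates 1 and 2, so these correlations cannot settle a pairing. The number as a block gave 5031 higher and 4950 lower genes. Across all alternatives, 96 values of the main results stayed within 1.5 times or kept their call, ERBB3 included, and 11 did not. The count of genes at least 2-fold lower, 622, was 1194 with the replicate block, 1132 with quality weights, and 328 to 1193 when 1 library was left out. With the block, DMSO replicate 3 and panobinostat replicate 4 have no same-numbered partner, so the treatment effect rests on replicates 1 and 2. The weights gave panobinostat replicate 4 a weight of 0.118. Without panobinostat replicate 1 or 2, replicate 4 carries more of the panobinostat mean. Over the genes at least 2-fold lower without replicate 4, its median log2 change was −0.51, against −1.28 and −1.30 in replicates 1 and 2. How much of the lower counts this accounts for was not tested. The lists called, 6 higher and 6 lower, were 10 and 10 with no filter, where 28673 genes were tested, 0 and 0 with an estimated correlation, and 23 and 13 with fry, whose test does not compare lists with other genes. Leaving out 1 library gave 3105 to 5024 genes higher, 2660 to 4969 lower, 1234 to 1698 at least 2-fold higher, 6 to 9 lists higher and 5 to 8 lists lower. ERBB3 stayed called in every alternative, at a log2 fold change of 3.01 to 3.51. For single lists 545 values were the same, 45 gained a call, 17 lost it and 1 turned in the direction of camera. That list was the luminal breast markers, whose median was 0.80 with no filter (camera adjusted p = 0.866, in a range of 0.280 to 0.866 over its alternatives), and the cause was not tested. The median of oxidative phosphorylation changed sign with no turn in camera direction, from 0.003 to −0.0003 without panobinostat replicate 4. For the named genes other than ERBB3, 3983 values were the same, 119 gained a call, 211 lost it (41 with no filter, 14 with the DESeq2 Wald test, 5 with library size only, 4 with upper-quartile factors and 147 on leaving out 1 library) and 37 changed sign, all in genes that were not called. The cause of the calls lost with no filter was not tested. Depth limits weakly expressed genes, since 16710 were left out by the filter on counts. In simulated counts, with far fewer changed genes than in the data, 47% of genes changed by 0.5 on the log2 scale were recovered. How much of this is due to depth and how much to the spread between libraries was not tested.

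With no filter the log2 fold change was −0.020 for H3-3A, −0.029 for HDAC2, −0.0031 for NEK2, −0.0088 for PTTG1, −0.045 for CLDN7, −0.033 for TUBA4A, −0.050 for CD8A and −0.012 for TNNT1. With upper-quartile factors the log2 fold change was 0.0049 for CDC20. With library size only the log2 fold change was 0.020 for CDC20 and 0.013 for RGS5. With the replicate block the log2 fold change was 0.0066 for CDC20, −0.12 for SYT1 and 0.23 for TMSB15B. With quality weights the log2 fold change was 0.0048 for CDC20, −0.067 for CD8A and 0.029 for RGS5. With the DESeq2 Wald test the log2 fold change was −0.053 for CD8A. Leaving out 1 library gave ranges of −0.018 to 0.058 for H3-3A, −0.013 to 0.056 for HDAC2, −0.039 to 0.0056 for CDC20, −0.057 to 0.089 for CLDN7, −0.59 to 0.030 for ALDH1A3, −0.0056 to 0.25 for SYT1, −0.0047 to 0.044 for TUBA4A, −0.48 to 0.073 for TMSB15B, −0.081 to 0.061 for TNFSF4, −0.27 to 0.22 for CD8A and −0.27 to 0.10 for RGS5. The cause of these sign changes was not tested.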

Other observations

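The tests on panobinostat replicate 4, on gene families, on processed pseudogenes and on the mean as the centre of the length and GC trend were chosen only after the results were seen. Grouping protein-coding genes by the root of their symbol gave 133 families of at least 10 tested members, of which camera called 7. The IFT family, whose members carry cargo along cilia, rose, with 12 of 15 members higher, 0 lower and a median log2 fold change of 0.63 (camera adjusted p = 0.00820, and adjusted p = 0.713 with an estimated correlation). IFT88 (1.29 ± 0.16) and IFT20 (0.91 ± 0.12) were among them. The SRSF splicing factors fell, with 10 of 11 members lower and a median of −0.61 (camera adjusted p = 0.00547, and adjusted p = 0.713 with an estimated correlation), among them SRSF4 (−1.22 ± 0.26) and SRSF7 (−0.90 ± 0.16). SRSF4 was not called with no filter (edgeR adjusted p = 0.0797, and 3.68e-187 to 0.0797 over all its alternatives). The RPL, MCM, RBM, MRPL and DDX families also fell, with medians of −0.23, −0.78, −0.44, −0.26 and −0.33, and also at adjusted p = 0.713 with an estimated correlation. With an estimated correlation, camera called 0 of the 133 families, and 0 had an unadjusted p under 0.05. That form of the test could call little with 6 libraries, so it does not decide whether these families moved. Of 347 processed pseudogenes tested, which can take reads of their parent genes, 15 rose and 58 fell, with a median of −0.24.

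Panobinostat replicate 4 lay between the other panobinostat libraries and DMSO. The tables argue against lower depth, since panobinostat replicate 2 had fewer counts (5.39 in units of 1000000) and lay as far from DMSO as replicate 1. They also argue against a DMSO library with a wrong label. The genes used were at least 2-fold changed without replicate 4, with a mean of at least 10 CPM in DMSO or in replicates 1 and 2. Of the 1028 that rose, 0.389% lay at or below the highest DMSO value in replicate 4. On the linear CPM scale the median share of replicate 4 on the way from the DMSO mean to replicates 1 and 2 was 0.485 in 1028 genes that rose (95% bootstrap interval 0.480 to 0.490) and 0.487 in 851 that fell (0.481 to 0.492), a difference of 0.0021, while on the log scale the shares were 0.629 and 0.371, a difference of 0.258 that a response scaled down alike for every gene on that scale would not give. The intervals resample genes of 1 library, which are not independent replicates. They do not measure how uncertain the share of that library is. An equal mixture of DMSO replicate 2 and panobinostat replicate 2, set against the other libraries, gave 0.496 and 0.495. An equal mixture gives about such shares by construction. Both of its libraries also took part in the choice of the genes. Replicate 4 took no part in that choice, which can lower its own share. A candidate explanation is that RNA or cells of both treatments are mixed in this library, or that about that share of the cells did not respond, and these data do not separate the 2.

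Of the genes changed at least 2-fold, 70.0% were higher, and this share was 58.7% without panobinostat replicate 4, a difference of 11.3 percentage points, so the intermediate levels of that library may account for part of the excess. Background reads that lift weakly expressed genes are argued against as the whole cause, since 16.2% of the 4447 least expressed tested genes were called lower, beside 32.4% called higher. For gene length and GC content, the outcome depends on how the residuals are centred. With the trend removed, 55.01% were higher when residuals were centred on the median (1185 against 969 genes). When they were centred on the mean, 67.6% were higher (1402 against 671). The centres, 0.0024 and 0.133 on the log2 scale, shift all genes alike. The gap between these shares is therefore not due to length or GC content. By the rule set before the result, the share centred on the median left length and GC content undecided as a cause. With the mean kept, the share moved from 70.0% to 67.6%. An argument against length and GC content as the main cause therefore rests on the later choice of centre. The median was the first choice, and the mean was added after its result was seen. The trend held 1.76% of the variance of the log2 fold changes of 13322 genes.

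As a hypothesis written before the result was seen, weakly expressed genes were to rise more, and the median log2 fold change of the 2668 genes of lowest mean expression lay 0.31 above that of the 2669 of highest, 0.22 against −0.09. The same counts enter the level and the fold change, so part of this may follow from how genes were ranked. A second hypothesis, that genes with a long genomic span fall more, was not borne out: the median of the longest 2665 genes lay 0.0794 above that of the shortest 2664.

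The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 4032 higher and 3821 lower genes with edgeR, 1451 and 622 of them at least 2-fold, and the highest other split gave 0 for each, with 192 genes at an unadjusted p under 0.05 against 8519. In these counts of genes 1 of the 10 splits, the real one, had as many. Every other split puts libraries of both treatments in each group, so the treatment effect enters its spread. The 0 of those splits is therefore no measure of chance. A split and its mirror count once, so the larger of its directions was taken for each other split. For lists the real split gave 6 higher and 6 lower with camera, and 2 of the 10 splits then had 6 in a direction. The other was DMSO replicates 1 and 2 with panobinostat replicate 4 against the rest, with 6 in one direction and 4 in the opposite one, so no other split had 6 in both.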
